A study of Ovis aries with 2 samples.

How the data were processed

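Nuclear RNA of sheep cerebral cortex was measured by droplet-based single-nucleus RNA sequencing in 2 libraries, 1 from tissue taken straight to nuclei isolation (pre-processed) and 1 from tissue that first went through debris and red blood cell removal (post-processed). The series description speaks of tissue from a single adult ewe, and the labels give an age range of 18 to 36 months and the same batch for both libraries. Groups were taken from the sample titles. The treatment label of the post-processed library repeats the wording of the other library on debris and red cell removal, which contradicts its title and the series description, so the direction of every comparison rests on the titles.

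The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, per the values in the files. The submitters' processing notes name DRAGEN, and the series description names Seurat for the later steps. The version of DRAGEN, the genome build, the annotation and the rule by which barcodes were called as nuclei are not given in the sources used here, so no coordinates are printed. The barcode calls differ in depth between the libraries. The shallowest pre-processed barcode had 904 UMIs, and the shallowest post-processed barcode had 44.

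Both matrices as used here list the same 13765 features with 12652 distinct symbols, all of which were found in the RefSeq gene table of the ARS-UI_Ramb_v3.0 assembly. By that table the listed genes are those of chromosomes 1 to 8 and part of chromosome 9, which make 9847 of 21300 protein-coding genes, or 46.23%. Genes of chromosomes 10 to 26, of the X chromosome and of the mitochondrial genome were not analysed here. UMI totals, counts per 1000000 UMIs (CPM) and counts of detected genes therefore refer to the listed genes only and are not the depth of the whole libraries. The markers MBP, GFAP, AQP4, GAD1, SLC17A7, SNAP25 and RBFOX3 and the haemoglobin genes are among those not analysed here. Because no mitochondrially encoded gene was listed, the planned limit on mitochondrial UMIs could not be applied.

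Barcodes with at least 100 detected genes were kept as nuclei, which left 2125 of 2125 pre-processed and 494 of 905 post-processed barcodes. The study states about 5000 nuclei captured per condition. Both libraries were clustered together in Seurat 5.3.0 under R 4.3.3 (log-normalization to 10000, 2000 variable genes, 30 principal components, Louvain resolution 0.5), without integration. Scrublet, run through scanpy 1.11.5, called 4 of 2125 pre-processed nuclei and 0 of 494 post-processed nuclei as doublets, so it made practically no calls. No doublets were removed in the main setting.

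Cell class names carry the ending "-like" and come from marker lists fixed before the data were examined, as were the comparisons, the other gene lists and the rule for named genes. GRIN1, STMN2, JUN and VCAN each stand in 2 lists. The scoring rule that turns markers into names was not fixed beforehand. 2 naming rules were tried, both written after the clusters, their leading genes and their numbers of nuclei per library had been seen. The first compared each marker with its mean CPM over the other clusters and left a cluster unnamed also when its 10 leading genes held as many markers of another class as of its own. It left 5 clusters closest to neurons unnamed, because a mean taken over many neuronal clusters hides markers they share. The second rule, used here, compares each marker with the 25th percentile over the other clusters, asks for at least 3 markers raised 1.5-fold, and leaves a cluster unnamed only when another class has more markers among its 10 leading genes. Excitatory, inhibitory and pan-neuronal lists were merged into 1 neuronal class, also after the clusters were seen. A cluster with none of its markers among its 10 leading genes was left unnamed when its median UMIs lay under its library's median divided by 2. That divisor was set after the data were seen. With a divisor of 3, the limit would have been 222.5 UMIs and the post-processed cluster 5, at a median of 230 UMIs, would have been called microglia-like. Shares are given both ways.

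With 1 library per condition from 1 animal nothing measures the spread between preparations. No significance test between the libraries was run and no p-value is given. Shares above 0 carry exact Clopper-Pearson 95% intervals, and for a share of 0 the limit given is 3 counts divided by the number of nuclei. Sums carry exact Poisson intervals, and ratios exact conditional binomial intervals. All of these cover counting error only. Ratios are log2 of post-processed over pre-processed CPM with 0.5 counts added. A fold against 0 UMIs is a bound computed with 3 counts in the library at 0. Shares of nuclei with a UMI were computed after thinning each nucleus to 200 UMIs, which left out 89 post-processed nuclei and no pre-processed ones. For each gene list, the median log2 ratio of members with at least 20 UMIs is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these 2 libraries only. Within a class, genes were compared where each library held at least 30 of its nuclei, which was the case for microglia-like and oligodendrocyte-like nuclei. Counting intervals of list medians came from 500 Poisson redraws. The fixed pattern for ribosomal protein genes also matched 4 genes of the RPS6K group, which encode kinases or kinase-like proteins. The list was kept as fixed, and its median without them is an added alternative.

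Named genes follow a fixed rule of size. Of each list, the 2 members with the highest mean CPM and the 2 with the largest absolute ratio were eligible. Over all nuclei, the 10 highest and 10 lowest ratios among genes with at least 50 UMIs in a library were taken, and within a class the 5 highest and 5 lowest among genes with at least 30 UMIs. The 5 genes with the most UMIs in each library were also taken. At most 2 genes without a symbol could be named per direction, and none is named in the text. Other genes are named only as members of a list or as leading genes of a cluster.

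The ratio, its interval and the list percentile were tested on simulated Poisson counts drawn from the averaged profile of the summed libraries, with 200 genes changed by known folds. For the sums over all nuclei, the interval held the true ratio for 95.8% of 6443 genes. The interval assumes such counts, so this checks the computation and not the spread between nuclei or preparations. Of the genes changed 2-fold, 4-fold and 8-fold, 100%, 94.0% and 92.4% came out with the right sign and within 1 log2 unit. A list of 8 raised genes reached percentile 100, and 5.50% of 200 unchanged lists fell under percentile 5 or over 95.

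Alternatives fixed before the data were examined were other minimums of detected genes (none, 200 and 500), other cluster settings, each library clustered on its own, doublet removal, classes from marker UMIs without clustering, other thinning depths, the median of gene ratios as the scale, a prior of 2 counts and other UMI minimums. The first naming rule, counting cluster 5 as microglia-like, 2 other ways to pick the nuclei of a class and the ribosomal list without the RPS6K genes were added after the data were seen. The scripts ran under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.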

Results

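Cortical nuclei of an adult sheep were profiled in 2 libraries that differ in how the tissue was handled before nuclei isolation, to ask how debris and red blood cell removal affects the makeup of neural cell types. There was 1 library per condition and no replicate, so each difference below is between 2 libraries and all intervals cover counting error only. Over the listed genes, the pre-processed library had 9580441 UMIs in 2125 barcodes, with a median of 2524 UMIs and 1203 detected genes per barcode. The post-processed library had 794203 UMIs in 905 barcodes, with a median of 146 UMIs and 118 detected genes. Of the post-processed barcodes 494 had at least 100 detected genes, with a median of 667.5 UMIs, and 411 had fewer. Every pre-processed barcode passed that minimum.

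**Figure D1:**
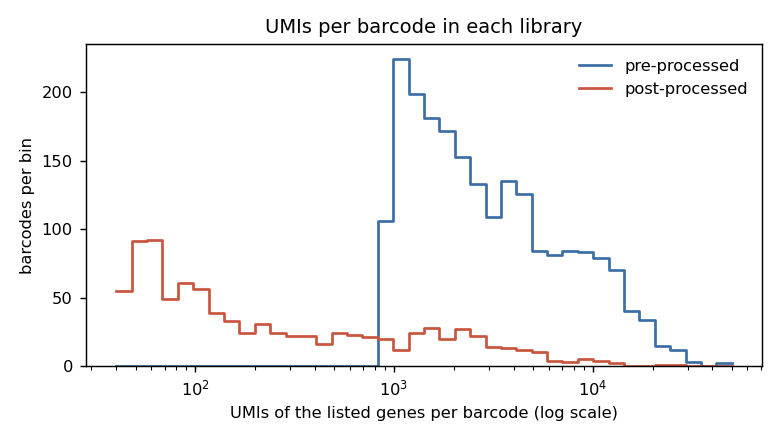
Number of barcodes (vertical axis) by UMIs of the listed genes per barcode (horizontal axis, log scale) in the pre-processed and post-processed library. The pre-processed barcodes start at 904 UMIs, and the post-processed barcodes reach down to 44 UMIs with a median of 146.

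The first comparison concerned the share of each cell class. Neuron-like nuclei made up 986 of 2125 pre-processed nuclei, or 46.4% (95% interval 44.3 to 48.5%), and 0 of 494 post-processed nuclei, which in the main setting allows a share of up to 0.607%. Some alternatives named a few post-processed nuclei neuron-like, 4 of 494 at resolution 0.2, 1 of 405 after thinning to 200 UMIs and 5 of 494, or 1.01% (0.329 to 2.35%), from marker UMIs without clustering. Astrocyte-like nuclei made up 16.8% of pre-processed nuclei (15.2 to 18.5%) and 0.405% of post-processed nuclei (0.0491 to 1.45%). Oligodendrocyte precursor-like nuclei made up 5.13% before processing (4.23 to 6.15%) and 0 of 494 after it, with 3 of 405 after thinning and 13 of 494, or 2.63% (1.41 to 4.46%), from marker UMIs. Microglia-like nuclei were 85 of 2125, or 4.0% (3.21 to 4.92%), in the pre-processed library. In the post-processed library they were 180 of 494, or 36.4% (32.2 to 40.9%), and 406 of 494, or 82.2% (78.5 to 85.5%), if the shallow cluster 5 is counted with them. Over all alternative settings the microglia-like difference lay between 27.0 and 86.3 percentage points. The upper end is from the setting with no minimum of genes, where 817 of 905 post-processed barcodes took that name and none stayed unnamed. That setting takes in the 411 barcodes under 100 genes, for which nuclei and free RNA are not told apart. Endothelial-like nuclei were 0.376% (0.163 to 0.740%) and 5.87% (3.97 to 8.32%), but at resolution 0.2 and after thinning no nucleus of either library took that name, and with libraries clustered apart 0 of 2125 and 33 of 494 did.

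Oligodendrocyte-like nuclei made up 8.42% of pre-processed nuclei (7.28 to 9.69%) and 11.5% of post-processed nuclei (8.86 to 14.7%). The direction of that difference of 3.11 percentage points turned when no minimum of detected genes was set, where it was -2.05 points, and it reached 14.5 points when classes were taken from marker UMIs without clustering. Barcodes were called at different depths in the 2 libraries, from 904 UMIs up before processing and from 44 UMIs up after it.

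3 clusters stayed unnamed. Cluster 5 held 226 of 494 post-processed nuclei, or 45.7% (41.3 to 50.3%), and 1 pre-processed nucleus, at a median of 230 UMIs. Its leading genes were THBS1, GNLY, SAMSN1, FOS and LAPTM5, and the microglial class was the closest by markers. Cluster 2 held 15.7% of pre-processed nuclei (14.2 to 17.3%), at a median of 1262 UMIs against 2524 in the whole library, and was not tested for free RNA. It was led by S100B and NEFL, markers of different classes. It had the neuronal markers SYT1 at 6214 CPM and CAMK2A at 1977 CPM, and the astrocyte marker SLC4A4 at 653 CPM. Cluster 10 held 3.11% of pre-processed nuclei (2.41 to 3.93%), was led by SEMA3E, SYT6 and FOXP2, lay closest to the neuronal class and had MEGF11, an oligodendrocyte precursor marker, among its leading genes. Neither had a post-processed nucleus. Most clusters came almost wholly from 1 library, and with 1 library per condition a feature of the library and a cell type are not separated in such a cluster. Under the naming rule tried first, the neuron-like share of pre-processed nuclei was 14.0%, with 0 of 494 in the post-processed library. At resolution 0.2, where no nucleus stayed unnamed, the neuron-like share of pre-processed nuclei was 65.3%. The astrocyte-like difference of -16.4 points was -31.9 points when the 4 called doublets were removed before clustering. Astrocyte-like pre-processed nuclei then numbered 685 instead of 357, and unnamed ones 68 instead of 401. Cluster 2, with 334 nuclei, lay closest to the astrocyte class, so the change lay in which nuclei were named.

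**Figure D2:**
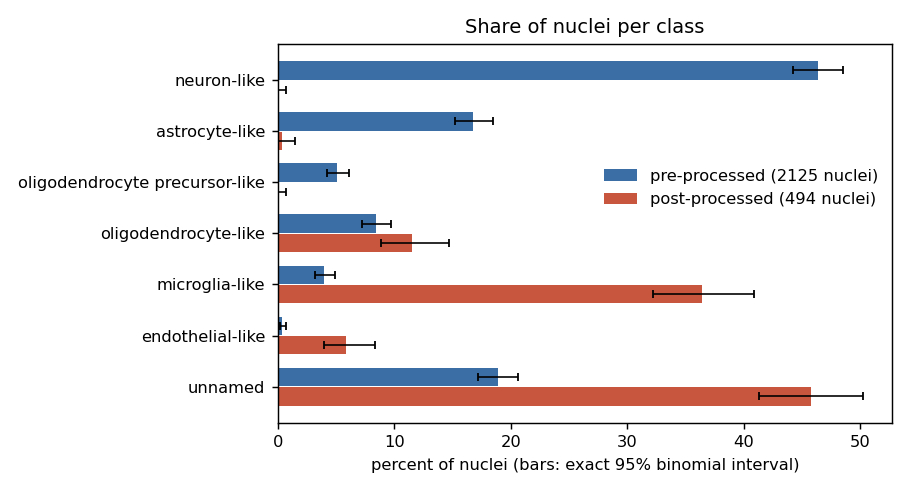
Percent of nuclei per class (horizontal axis) in the pre-processed library (2125 nuclei) and the post-processed library (494 nuclei), with exact 95% binomial intervals. Neuron-like nuclei stand at 46.4% against 0, and microglia-like nuclei at 4.0% against 36.4%, with another 45.7% of post-processed nuclei in the unnamed cluster 5.

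Marker expression in the sums over all nuclei was compared next. All 8 pan-neuronal genes had lower CPM in the post-processed library, 7 of them at least 2-fold, with a median log2 ratio of -6.28 at percentile 0 of matched random lists. With genes at 0 set to their bound, the median was -5.67. SYT1, a calcium sensor of synaptic vesicles, had 7338 CPM before and 51.0 CPM after processing, a log2 ratio of -7.15 (-7.66 to -6.72). GRIN1, the obligatory subunit of NMDA receptors, had 3338 UMIs before and 0 after, at least 88.9-fold lower. MAP2, a microtubule-associated protein, was the exception in size, with a log2 ratio of -0.36 (-0.45 to -0.27). Of its 1143 post-processed UMIs, 1004 lay in microglia-like nuclei, where its ratio was 0.10 (-0.10 to 0.30). All 6 excitatory neuron markers were at least 2-fold lower. The 6 inhibitory neuron markers were lower too, but PVALB, with 45 UMIs before and 0 after, can only be bounded as at least 1.2-fold lower. These lists had medians of -5.11 and -3.84, or -3.33 and -2.06 with genes at 0 set to their bound. CAMK2A, a kinase of excitatory synapses, had 11600 UMIs before and 3 after, a log2 ratio of -8.05 (-10.55 to -6.72).

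Astrocyte markers were lower as well, all 5 of them at least 2-fold, with a median of -2.49 at percentile 0.94. SLC4A4, a bicarbonate cotransporter, had 519 CPM before and 48.4 CPM after, a log2 ratio of -3.41 (-3.93 to -2.96). Of 7 oligodendrocyte precursor markers 6 were lower, 4 of them at least 2-fold, with a median of -2.25 at percentile 0.745.

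Microglial markers were higher in the post-processed library. All 8 were at least 2-fold higher, with a median log2 ratio of 4.71 at percentile 100. INPP5D, a lipid phosphatase of blood and immune cells, went from 108 to 2618 CPM, a log2 ratio of 4.60 (4.49 to 4.71), and P2RY12, a purinergic receptor of microglia, went from 74.6 to 1709 CPM. The complement genes C1QB and C1QC had ratios of 6.26 and 5.46. All 5 oligodendrocyte markers were at least 2-fold higher, with a median of 2.94 at percentile 99.7. Of their 2242 post-processed UMIs, 1132 lay in microglia-like nuclei and 905 in oligodendrocyte-like nuclei. UGT8, an enzyme of myelin lipid synthesis, went from 214 to 1123 CPM, and ERMN, a cytoskeletal protein of myelinating cells, had a ratio of 4.11 (3.86 to 4.37). All 6 endothelial markers were at least 2-fold higher, with a median of 3.62 at percentile 99.99.

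**Figure D3:**
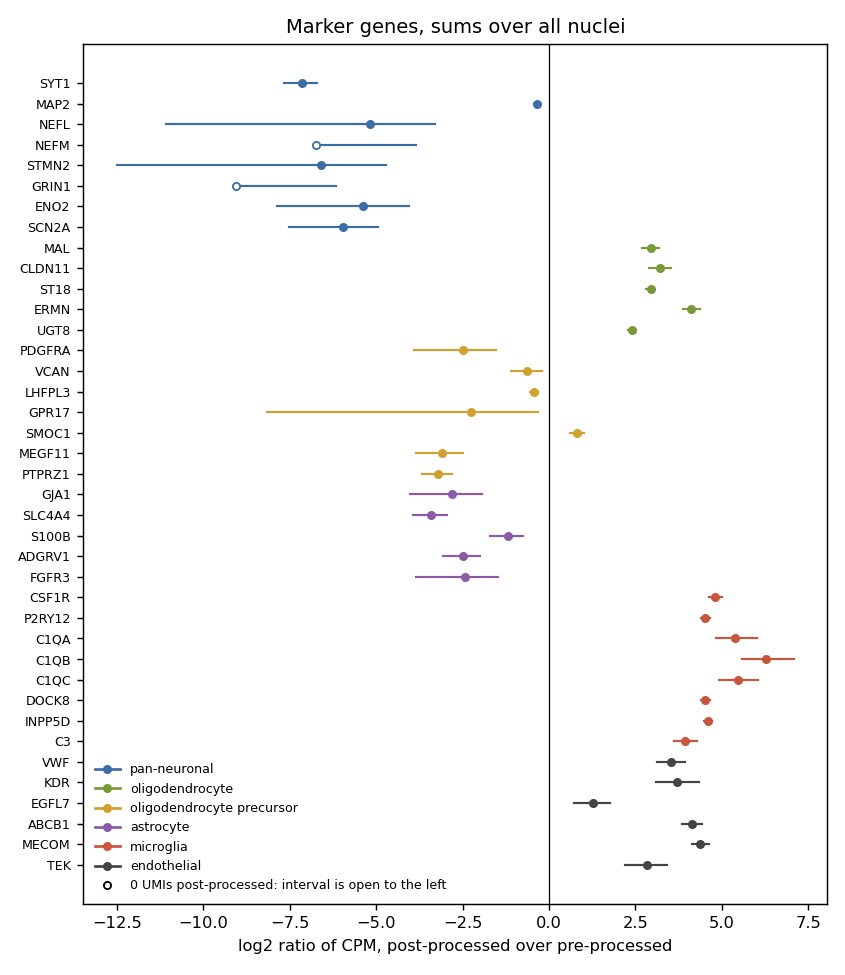
Log2 ratio of CPM, post-processed over pre-processed (horizontal axis), for each marker with at least 20 UMIs (vertical axis), coloured by list, with 95% counting intervals and open circles for genes with 0 post-processed UMIs. Pan-neuronal and astrocyte markers lie below 0, with MAP2 nearest to it at -0.36, and microglial, oligodendrocyte and endothelial markers lie above 0.

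Shares of nuclei with a UMI were compared at 200 UMIs per nucleus. SYT1 was seen in 55.9% of pre-processed nuclei (53.8 to 58.0%) and 0.741% of post-processed nuclei (0.153 to 2.15%), and unthinned in 89.2% and 6.28%. Its share in oligodendrocyte-like nuclei, which should lack it, was 8.94% before and 1.75% (0.0444 to 9.39%) after processing. INPP5D was seen in 3.39% and 38% of nuclei, unthinned in 13.6% and 60.7%, with 1.01% in pre-processed neuron-like and 1.75% in post-processed oligodendrocyte-like nuclei as background. UGT8 was seen in 7.29% and 14.6%, with a background of 0.811% in pre-processed neuron-like nuclei. Its share in post-processed microglia-like nuclei was 7.22%. That may not be background, since 27 nuclei of that class and library were named oligodendrocyte-like at resolution 1.0. Unthinned, UGT8 was seen in 28.7% and 27.5%, the other direction. The unthinned share also takes in the 89 shallow post-processed nuclei that thinning left out, so depth and the set of nuclei are not separated. SLC4A4 was seen in 10.4% and 1.73%, unthinned in 52.6% and 4.66%, with 2.23% in pre-processed and 0 of 57 in post-processed oligodendrocyte-like nuclei, the latter allowing up to 5.26%. In post-processed microglia-like nuclei its share was 0.556% (0.0141 to 3.06%). Median depths before thinning were 5086.5 UMIs in neuron-like and 1490 in oligodendrocyte-like pre-processed nuclei, and 2434 in oligodendrocyte-like and 1535 in microglia-like post-processed nuclei.

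Across all genes, the sums of the 2 libraries had a Spearman correlation of 0.588 over 6484 genes, which are not independent replicates. Taking the median of gene ratios as the scale shifted all log2 ratios by -0.31. The highest ratios belonged to HSPA6, DMP1, IL1A, HMOX1, FOS, SAMSN1, KLF2, ANXA1, EHD4 and TAGAP, between 6.77 and 9.80. HSPA6, an inducible heat shock protein, had 3 UMIs before and 248 after, a ratio of 1035-fold with a log2 interval of 8.45 to 12.30. IL1A, an inflammatory cytokine, went from 1.98 to 546 CPM, and HMOX1, a stress-induced enzyme of haem breakdown, from 0.939 to 222 CPM. The lowest ratios among genes with a symbol belonged to UNC13A, OLFM3, GRIN1, VWC2, SLC7A14, PCSK1, AK5, ICAM5, CAMK2A and KCNIP4. KCNIP4, a potassium channel partner, took the most UMIs of any gene in the pre-processed library (1.60%, followed by PTPRD, CADM2, NRXN3 and ADGRB3) and went from 15968 to 60.1 CPM. The genes with the most UMIs in the post-processed library were NKAIN2 (1.02%), NCKAP5, MAGI2, SLC24A2 and TMCC3.

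Other fixed lists followed over all nuclei, where the shares of cell classes differ too. Of 9 immediate early genes 8 were at least 2-fold higher and ARC, with 0 post-processed UMIs, was at least 4.37-fold lower, with a median of 2.76 at percentile 99.96. FOS went from 14.5 to 2216 CPM and JUN from 27.7 to 1481 CPM. All 4 measured genes of ex vivo microglial activation were at least 2-fold higher, with a median of 6.20 at percentile 100. The 3 heat shock genes had a median of 2.23 at percentile 96.0, and of 39 genes matched by the ribosomal pattern 38 were higher, with a median of 2.47 at percentile 100. Of 8 glutamate receptor genes 7 were lower, with a median of -5.29, while GRM8 was higher at 1.55 (1.48 to 1.62). All 7 GABA receptor genes and all 9 long synaptic genes were lower, with medians of -5.04 and -5.05. The lists on neurite outgrowth inhibition and on axon growth went both ways, with medians of -1.06 and -2.67. In the first, RTN4, which encodes Nogo, was higher at 1.56 (1.43 to 1.68) and NCAN, a matrix proteoglycan, lower at -4.94. In the second, JUN was higher and NTRK2 lower at -3.48, while KLF4 had 1 UMI before and 42 after (log2 interval 6.48 to 14.38) and STMN2 1826 before and 1 after (-12.49 to -4.71). Medians of the remaining lists were 1.60 for mural, 3.45 for fibroblast, 1.34 for hypoxia and glycolysis and 1.40 for oxidative phosphorylation. The fibroblast median rests on 3 genes. Of 311 post-processed COL1A2 UMIs, 277 lay in microglia-like nuclei, and of 70 COL6A3 UMIs, 37 lay in oligodendrocyte-like nuclei. For DCN the interval of -1.27 to 1.43 included 0. The lymphocyte and erythroid lists had 1 measured gene each, THEMIS at 2.17 and SLC25A37 at 0.44.

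Within microglia-like nuclei, 85 pre-processed against 180 post-processed, the immediate early genes stood apart from the class's own markers. All 8 measured immediate early genes had higher CPM in the post-processed library, 7 of them at least 2-fold, with a median log2 ratio of 3.43 (2.66 to 4.29) at percentile 100. The 8 microglial markers had a median of 0.22 at percentile 86.3, with 5 higher and 3 lower. They ranged from C1QB at 2.83 (1.45 to 5.35) to P2RY12 at -0.42 (-0.58 to -0.25). FOS had 1 UMI before and 1339 after, a ratio of 356-fold with a log2 interval of 5.99 to 13.78. JUN went from 68.5 to 1862 CPM, with a log2 ratio of 4.69 (3.83 to 5.90), and NR4A1 from 38.1 to 1258 CPM. At 200 UMIs per nucleus FOS was seen in 0 of 85 pre-processed microglia-like nuclei, which allows up to 3.53%, and in 38.9% of post-processed microglia-like nuclei (31.7 to 46.4%), against 5.26% of post-processed oligodendrocyte-like nuclei. The 3 heat shock genes had a median of 2.59, the 4 ex vivo activation genes 1.71 and the 37 genes of the ribosomal pattern 1.05. Among genes with a symbol, the highest ratios in this class were those of FOS, ANXA1, HSPA6, DNAJB1 and DUSP2, and the lowest those of CAMK2A, MLC1, SYT1, KCNIP4 and KCTD16. Of these, CAMK2A, SYT1 and KCNIP4 are known from neurons. SYT1 had 1218 CPM in pre-processed and 46.5 CPM in post-processed microglia-like nuclei. At resolution 1.0 the class fell into a microglia-like cluster of 57 pre-processed and 20 post-processed nuclei, and another of 1 and 127 nuclei, led by IL1A and with FOS among its leading genes. A further 27 pre-processed and 27 post-processed nuclei of the class went to a cluster named oligodendrocyte-like there, and 6 post-processed nuclei to an unnamed cluster. The immediate early median of the nuclei still named microglia-like was 3.27.

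**Figure D4:**
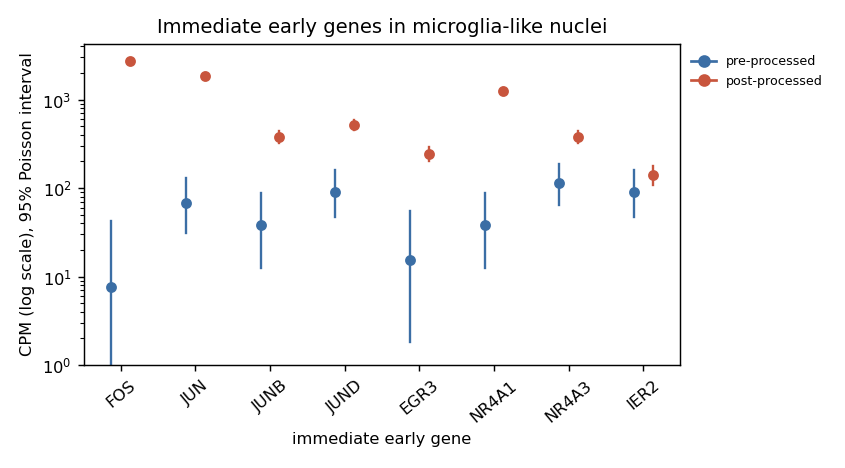
CPM (vertical axis, log scale) of the 8 immediate early genes with at least 20 UMIs in microglia-like nuclei of the pre-processed and the post-processed library, with 95% Poisson intervals. FOS, JUN and NR4A1 stand at 2707, 1862 and 1258 CPM after processing, and for IER2 the intervals of the libraries overlap.

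Within oligodendrocyte-like nuclei, 179 pre-processed against 57 post-processed, markers of the class differed less than neuronal genes did. The 5 oligodendrocyte markers had a median of 0.30 at percentile 89.6, and the 4 measured pan-neuronal genes one of -3.55, or -1.92 with genes at 0 set to their bound. FOS again had the highest ratio, from 1 to 44 UMIs, with a log2 interval of 4.0 to 11.89, followed among genes with a symbol by COL8A1, KYNU, EBF1 and FOXP2. The 3 measured immediate early genes had a median of 1.23 (0.23 to 2.34). That median is the ratio of JUN, which had 10 UMIs before and 11 after and an interval of its own of -0.14 to 2.63. For JUND the interval of -0.45 to 1.84 included 0 too. The list median was 3.95 at resolution 1.0, where a cluster of 27 and 27 nuclei took this name in addition. All nuclei of that cluster are microglia-like in the main setting, and DMP1, EHD4, ERMN and UGT8 are among its leading genes, so the value of 3.95 includes nuclei from that class. With classes taken from marker UMIs the median was 4.02, so this median depends on how nuclei were assigned. The lowest ratios were those of CAMK2A, GRIA1, KALRN, NRCAM and BCAN, each with 0 post-processed UMIs, CAMK2A at least 28.3-fold and BCAN at least 9.65-fold lower. CAMK2A, an excitatory neuron marker, had 610 CPM in pre-processed oligodendrocyte-like nuclei, and the pan-neuronal SYT1 had 674 CPM there. RNA of other cells in the pre-processed barcodes was not told apart from a change within oligodendrocytes.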

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

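The tests of cluster 5 and of immediate early UMIs per nucleus were chosen after the result was seen, and the other tests before their deciding values were computed but after the clusters had been looked at.

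The main setting leaves out the 411 post-processed barcodes under 100 detected genes, which enter the setting with no minimum of genes and some tests below. Their microglial markers summed to 7863 CPM (6876 to 8953) and their immediate early genes to 10312 CPM (9176 to 11550). They are listed because the sums pass the limit that a count of 0 allows, as those of any barcodes with free RNA of these genes would, so this alone does not tell nuclei from free RNA.

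Neuron-like nuclei were missing from the post-processed library in the main setting, with at most 5 of 494 under the alternatives. Shallow nuclei that cannot be recognised would need the pre-processed library to lose its neuron-like nuclei at 200 UMIs, but their share there was 63.9% (61.8 to 66.0%). This does not cover barcodes under 200 UMIs, which are 89 kept post-processed nuclei and the 411 barcodes under 100 genes, with at most 133 UMIs. Removal of neurons by the minimum of detected genes would need pan-neuronal CPM in the barcodes under 100 genes near the pre-processed level, but it was 16.2% of it (12 to 21.3%). That sum includes MAP2, which made 1143 of the 1193 pan-neuronal UMIs in the kept post-processed nuclei. In the barcodes under 100 genes SYT1 had 1 UMI and GRIN1 had 0. A loss of neurons through the extra processing, which the design names, stays open as an untested hypothesis, as does a failed or differently called preparation, since each condition has 1 library.

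Immediate early genes were higher in post-processed microglia-like nuclei. Dilution by free RNA before processing would move microglial markers alike, and more cytoplasmic RNA would raise ribosomal protein genes as much. The immediate early median lay 3.21 log2 units above the microglial markers (2.39 to 4.07) and 2.38 above the ribosomal pattern (1.57 to 3.25). The microglial markers were not uniform themselves, with 5 higher and 3 lower. Genes of the ribosomal pattern rose too, with a median of 1.05 (0.84 to 1.26), or 1.29 without the RPS6K genes. A like addition gives larger ratios to genes near 0 before, such as FOS with 1 UMI, so cytoplasmic RNA is not set aside. For free RNA of the post-processed library the tests went apart. In the test written beforehand, barcodes under 100 genes held immediate early genes at 138% of the CPM in microglia-like nuclei (122 to 155%), as that explanation predicts, but those barcodes were also rich in microglial markers, so the test could not part free RNA from remnants of microglia. In the test added later, oligodendrocyte-like nuclei held 6.31% as many immediate early UMIs per nucleus as microglia-like nuclei of the same library (4.94 to 7.94%). Endothelial-like nuclei held 31.0% (26.6 to 35.9%). Mean depths were 2442, 2748 and 1717 UMIs for oligodendrocyte-like, microglia-like and endothelial-like nuclei. Free RNA would give all a like number. These values are for the main assignment of nuclei only. Clustering had already sorted the barcodes by their genes, and the oligodendrocyte-like immediate early median depended on how nuclei were assigned. Part of the gap may come from that sorting, so this test does not decide on free RNA as the source. A response of microglia during the extra processing may account for the pattern and was not tested apart from other differences between the 2 libraries.

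Cluster 5 may hold free RNA and no nuclei, and free RNA would have the library's makeup. Its ratio of oligodendrocyte to microglial marker UMIs was 0.598 times that of all post-processed barcodes (0.496 to 0.719), which differs from equality but does not pass the 2-fold gap set for excluding free RNA. The ratio itself was 0.235 (0.195 to 0.282), near the 0.228 (0.213 to 0.243) of post-processed microglia-like nuclei, while barcodes under 100 genes had 0.386 (0.298 to 0.496) and all post-processed barcodes 0.393 (0.374 to 0.412). Genes of the ribosomal pattern summed to 21310 CPM (20236 to 22426) in cluster 5. That lay between 9356 CPM in post-processed microglia-like nuclei and 34316 CPM in barcodes under 100 genes. Shallow microglia and free RNA cannot be told apart from these values. Clustering had already sorted the barcodes by their genes, so part of the gap in the marker ratio may come from that sorting. No biological explanation was tested for this cluster.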

How the results depend on the processing

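The first naming rule, counting cluster 5 as microglia-like, taking the nuclei of a class by marker UMIs or at 500 genes, and the ribosomal list without the RPS6K genes were tried after the data were seen. No paired analysis was possible because each condition has 1 library. A stricter mitochondrial limit and totals without mitochondrial and haemoglobin genes were not run, since no such gene was analysed here. Of 148 alternative values of the main results, 99 stayed within the counting interval with the same direction, 47 moved beyond it and 2 reversed. For single genes these numbers were 123, 3 and 0 of 126. The cause was not tested except where said. Thinning to 400 UMIs leaves out 186 post-processed nuclei, and no interval covers the spread between preparations.

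Share differences are post-processed minus pre-processed, in percentage points. The neuron-like difference of -46.4 was -40.7 with at least 200 genes, -64.5 at resolution 0.2, -42.8 with 15 principal components, -43.2 with each library clustered on its own, -63.7 after thinning to 200 UMIs, -60.5 from marker UMIs without clustering and -14.0 under the first naming rule. The astrocyte-like difference of -16.4 was -31.9 without called doublets, where unnamed pre-processed nuclei fell from 401 to 68, and -13.7 from marker UMIs. The oligodendrocyte-like difference of 3.11 reversed to -2.05 with no minimum of genes. It was 7.97 with at least 200 genes, 13.9 with at least 500, 7.36 at resolution 1.0, 7.67 with 15 principal components, 7.20 with libraries clustered apart, 10.4 after thinning and 14.5 from marker UMIs. The microglia-like difference of 32.4 was 86.3 with no minimum, 72.1 with at least 200 genes, 62.6 with at least 500, 82.9 at resolution 0.2, 27.0 at resolution 1.0, 73.9 after thinning, 53.6 from marker UMIs and 78.1 with cluster 5, so the main value lies near the low end. With no minimum and at resolution 0.2 no post-processed barcode stayed unnamed. Those values, like the one with cluster 5, take in shallow barcodes that are not told apart from free RNA.

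The share of nuclei with a UMI of SYT1 differed by -68.0 points at 400 UMIs and -82.9 unthinned, that of INPP5D by 51.6 and 47.2, and that of SLC4A4 by -16.0 and -47.9. For UGT8 the difference of 7.27 reversed to -1.18 unthinned, where pre-processed nuclei are deeper and 494 instead of 405 post-processed nuclei enter. With the median of gene ratios as the scale, which shifts every gene alike, log2 ratios were 2.08 for UGT8 and 4.29 for INPP5D, and list medians 2.63 for oligodendrocyte, 4.40 for microglia and 2.45 for immediate early genes. A prior of 2 counts gave a pan-neuronal median of -5.23. The ribosomal median in microglia-like nuclei was 1.29 without the RPS6K genes. The Spearman correlation of 0.588 was 0.593 with at least 500 genes, 0.648 over genes with at least 20 UMIs and 0.528 with at least 100. At resolution 1.0 and from marker UMIs the immediate early median in oligodendrocyte-like nuclei was 3.95, with 27 and 27 nuclei from the microglia-like class of the main setting, and 4.02, and correlations were 0.710 and 0.663 there and 0.703 and 0.691 in microglia-like nuclei. The median post-processed UMIs per barcode were 667.5 with at least 100 genes.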
